A study of Rattus norvegicus with 13 samples.

How the data were processed

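RNA was measured in the whole hypothalamus of 13 rats, 7 raised on standard chow and 6 raised on a high-fructose diet. Per the labels' protocols, tissue was lysed and homogenised with Trizol and QiaShredder, an RNeasy kit was used for the RNA, and mRNA libraries were made from 1 µg of total RNA. The deposited values are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, in 1 table with 1 column per rat. Per the submitters' processing notes, STAR 2.3.0e, Cufflinks 2.1.1 and Cuffdiff were used with the rat genome build rn5. The version of Cuffdiff, the settings and role of each tool, and any scaling between libraries are not given in the sources used here. Columns were matched to rats by their names, groups were taken from the labels, and replicates were numbered in accession order, so that a number names a rat and pairs nothing.

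The table had 17366 rows, of which 2954 were listed at 0 in all 13 rats. A further 129 rows joined the symbols of several genes, and 940 carried a locus suffix, and both kinds were kept as the table gives them. Globin genes and other close copies, such as Hba1 and Hba2, can share reads, so their split between copies is uncertain. A value of 0 in an FPKM table can be a failed estimate, and Npy, which the named-gene rule holds, was listed at 0 in all 13 rats and is given no mean or fold change.

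No read counts are used here and the depth of each library is unknown. From the spacing of low FPKM values over 1821 rows, the value of 1 read relative to the first chow rat lay between 0.871 and 1.23, which is a rough estimate of relative depth alone. The precision of each value therefore rests on the spread between rats, 7 and 6 per diet. The rats were separate animals housed in pairs, and which rats shared a cage is not given in the sources used here, so whether cage mates were independent is unknown. The same holds for sex, batch and the injection of each rat, and no covariate could be entered for them.

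Values were analysed as log2(FPKM + 0.5). Genes with a mean of at least 0.5 FPKM over the 13 rats were tested, 11837 in all, with limma 3.58.1 in R 4.3.3 (empirical Bayes moderation with an intensity trend, two-sided). Benjamini-Hochberg adjustment ran over all genes tested, and an adjusted p under 0.05 was called a change. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. Errors of log2 fold changes are SE and errors of FPKM are SD. Each gene was also tested with an exact two-sided permutation test over the 1716 splits of the 13 rats into 7 and 6.

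Gene lists, 48 in number, were fixed before the data were examined. Of their 775 symbols 737 were matched in the table, 5 of them by a synonym and 4 in a joined row. The 46 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. The mitochondrially encoded transcripts had 0 members in the table and the sex linked genes 1 tested member, so neither was tested. Camera with an estimated correlation and limma's fry, which tests whether a list's genes move on balance 1 way, were run beside it. The level of a list was the mean of log2(FPKM + 0.5) over its tested members in each rat, compared between diets by an exact two-sided permutation test. Profiles over all genes were compared by the share of variance between diets, with an exact one-sided permutation test, and by principal components. Lists of midbrain dopamine neurons and of midbrain regional genes outside dopamine neurons were added after the fitted genes were seen, and a list of leukocyte genes was added before its values were seen. The levels of the latter pair were taken over members above 0 in at least 1 rat.

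Genes named in the text followed a rule fixed before the data were examined. It takes the 15 rising and 15 falling genes with the smallest p among those passing, with predicted symbols passed over, a fixed set of 19 hypothalamic and metabolic genes, and the 3 leading members of each of the 8 called lists with the smallest p. Of these genes 2 are not given in the text, though the counts over named genes hold them. Other genes named are members of the fixed or added lists, or were singled out, and were chosen after their values were seen.

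The alternatives were pseudocounts of 0.1 and 1, no filter or a mean of at least 2 FPKM, quantile normalization, median-ratio scaling, array weights, robust empirical Bayes, the exact permutation test per gene, an adjusted p under 0.1, camera with an estimated correlation, fry, and leaving out each rat in turn. Fits with the level of the thalamus, midbrain dopamine neuron or blood cell list as a covariate were added after the data were seen. Median-ratio factors lay between 0.99977 and 1.00767, so that scaling changes little here. The procedure was tested on simulated data for 11837 genes in the 7 and 6 rats with 200 genes changed. Of the simulated changes, limma recovered 54 of 67 genes at 1.5-fold (80.6%), 65 of 67 at 2-fold (97.0%) and 66 of 66 at 4-fold, with 9 false calls. The simulation drew each gene independently and so left out the correlation between genes. It cannot tell how many false calls such correlation gives in these data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.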

Results

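RNA of the whole hypothalamus was sequenced from 13 rats, 7 on standard chow with 0.30% fructose and 6 on a diet with 55% fructose. The diets began on postnatal day 25. The rats were fasted on day 79 and killed on day 80, 1 h after an intraperitoneal injection of glucose (2 g per kg) or saline. In the whole cohort 31 rats were given glucose and 29 saline, and which of the 13 sequenced rats received which is not given in the sources used here. Total FPKM ranged from 556902 to 608058 per rat, and 13156 to 13384 rows were above 0. Neither the total (exact two-sided permutation p = 0.192) nor the number of rows above 0 (exact permutation p = 0.174) differed between diets beyond the spread between rats. No columns were identical, and Pearson r across genes between rats, which are not independent replicates across genes, lay between 0.970 and 0.991.

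The comparison asked which hypothalamic transcripts differed between rats raised on fructose and on chow. By camera with a preset correlation, the lists of monoamine and histamine neurons, of the interferon response and antigen presentation, of blood cells and of the meninges were among those higher on fructose, and the lists of the thalamus, of GABA receptors and of the circadian clock among those lower. With an estimated correlation 0 of 46 lists were called. The adjusted p of the lists above was then 0.0555, 0.106, 0.122, 0.264, 0.336, 0.328 and 0.336, in that order. Of 11837 genes tested, 466 changed (limma, adjusted p under 0.05), 197 of them higher and 269 lower on fructose. The median absolute log2 fold change of these was 0.51, and 76 changed at least 2-fold, 42 higher and 34 lower. Diet accounted for 23.2% of the variance over all genes (exact one-sided permutation p = 0.00175), and the first principal component, with 28.9% of the variance, differed between diets (exact permutation p = 0.00175, adjusted p = 0.00524). In 190 genes the 6 fructose rats and the 7 chow rats did not overlap, against 13.8 genes (0.117%) given by chance. At an unadjusted p under 0.05 limma found 2269 genes. The exact permutation test per gene found 2223 at that level and 0 after adjustment. At the smallest p it can give, 0.000583, stood 104 genes, where 138 would have passed, and the smallest adjusted p was 0.0663.

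The number of genes that changed depended on single rats. It was 859 without chow replicate 1 and 89 without chow replicate 2. It was 304 without chow replicate 3, 103 without chow replicate 4, 187 without chow replicate 5 and 153 without chow replicate 7. It was 147 without fructose replicate 2, 83 without fructose replicate 4 and 113 without fructose replicate 6. In every one of the 13 fits with 1 rat left out, 70 of the 466 genes changed, 51 higher and 19 lower. Outside the rule for named genes, 41 changed genes are given as examples, chosen after their values were seen, and 10 of them (Drd2, Hrh3, Kcnj12, Col5a1, Col6a2, Gipr, Nkx6-1, Uncx, Emx2 and Ppp1r1b) kept their calls in all 13 fits. Of the 41, 31 lost their calls without chow replicate 2, 29 each without chow replicate 4, fructose replicate 4 or fructose replicate 6, 27 each without chow replicate 7 or fructose replicate 2, 19 without chow replicate 5, 13 each without chow replicate 3 or fructose replicate 3, 10 without chow replicate 6, 9 without fructose replicate 1, and 2 each without chow replicate 1 or fructose replicate 5. The highest adjusted p among these was 0.113, for Gabra4.

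**Figure D1:**
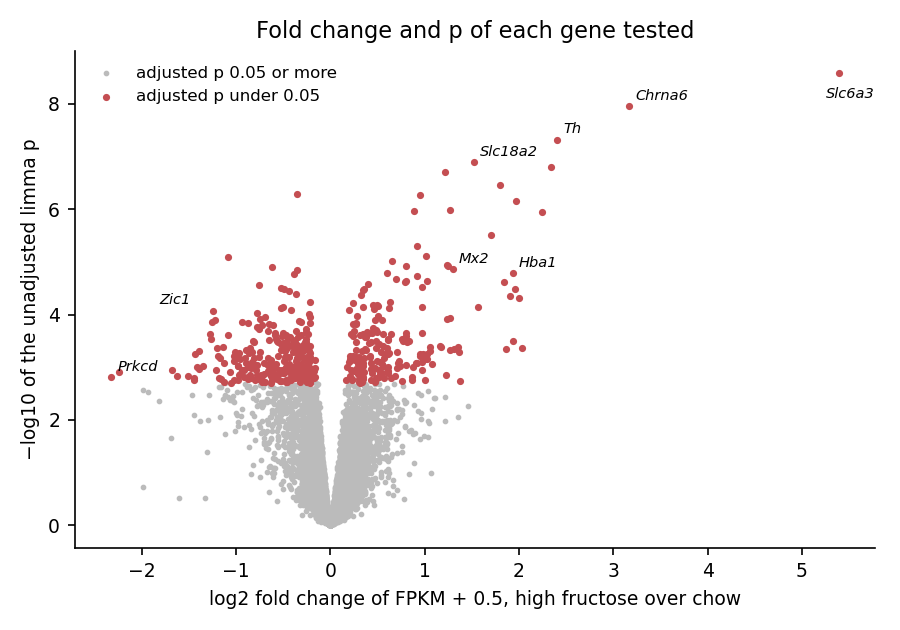
Log2 fold change (fructose minus chow, log2(FPKM + 0.5) scale, horizontal axis) against the unadjusted limma p on a negative log10 scale (vertical axis) for the 11837 genes tested, with the 466 genes at an adjusted p under 0.05 in colour. Genes of dopamine neurons lie farthest to the upper right, with Slc6a3 at 5.39.

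The 5 largest rises on the log2 scale were in genes known from dopamine neurons. Slc6a3, the dopamine transporter, stood at 1.36 ± 2.04 FPKM (SD, n = 7) on chow and 63.4 ± 33.6 FPKM (SD, n = 6) on fructose, a log2 fold change of 5.39 ± 0.43 (SE, limma adjusted p = 3.12e-05). Th, the rate-limiting enzyme of catecholamine synthesis, rose from 22.1 ± 5.03 to 125 ± 46.4 FPKM, by 2.40 ± 0.24 on the log2 scale (adjusted p = 0.000189). Slc18a2, the vesicular monoamine transporter, rose by 1.52 ± 0.16 and Ddc, aromatic L-amino acid decarboxylase, by 1.26 ± 0.16 (adjusted p = 0.000376 and 0.00104). The nicotinic receptor subunits Chrna6, Chrnb3 and Chrna5 rose by 3.17 ± 0.28, 2.34 ± 0.26 and 1.97 ± 0.24. With pseudocounts of 1 and 0.1 the rise was 1.73 and 3.57 for Chrnb3, and 1.44 and 3.01 for Chrna5. Slc10a4, a vesicular transporter of monoaminergic and cholinergic neurons, rose by 2.25 ± 0.29, Aldh1a1, an aldehyde dehydrogenase, by 1.22 ± 0.14, Sncg, gamma-synuclein, by 1.02 ± 0.15 and Ret, a receptor of glial cell line-derived growth factors, by 0.95 ± 0.11. For each of these 11 genes, all 6 fructose rats lay above all 7 chow rats.

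Of the 15 tested genes of monoamine and histamine neurons, 6 rose, 1 fell and 8 did not pass. Adjusted over the list alone, 10 passed. Those that rose were Slc6a3, Th, Slc18a2, Ddc, the dopamine receptor Drd2 (0.92 ± 0.15) and Gch1 (0.92 ± 0.22), an enzyme of tetrahydrobiopterin synthesis, whereas the histamine receptor Hrh3 fell (-0.69 ± 0.13). The list as a whole was higher on fructose (camera adjusted p = 3.00e-06, median log2 fold change 0.50), with an adjusted p = 0.0555 with an estimated correlation. Its level was 3.46 ± 0.14 (SD, n = 7) on chow and 4.32 ± 0.13 (SD, n = 6) on fructose, higher in 6 of 6 fructose rats than in any chow rat (exact permutation p = 0.000583, the smallest the splits allow, adjusted p = 0.00894). On a list of midbrain dopamine neurons, chosen after the values were seen, 19 of 22 tested genes rose. A list of midbrain regional genes outside dopamine neurons, also chosen after, was higher too, at -0.24 ± 0.08 on chow and -0.06 ± 0.09 on fructose (exact permutation p = 0.00466, 5 of 6 fructose rats above all chow rats). Of its 5 tested members 1, Sox14, rose (0.73 ± 0.18, limma adjusted p = 0.0389), a call kept with 1 rat left out only without chow replicate 1, fructose replicate 1 or fructose replicate 5.

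**Figure D2:**
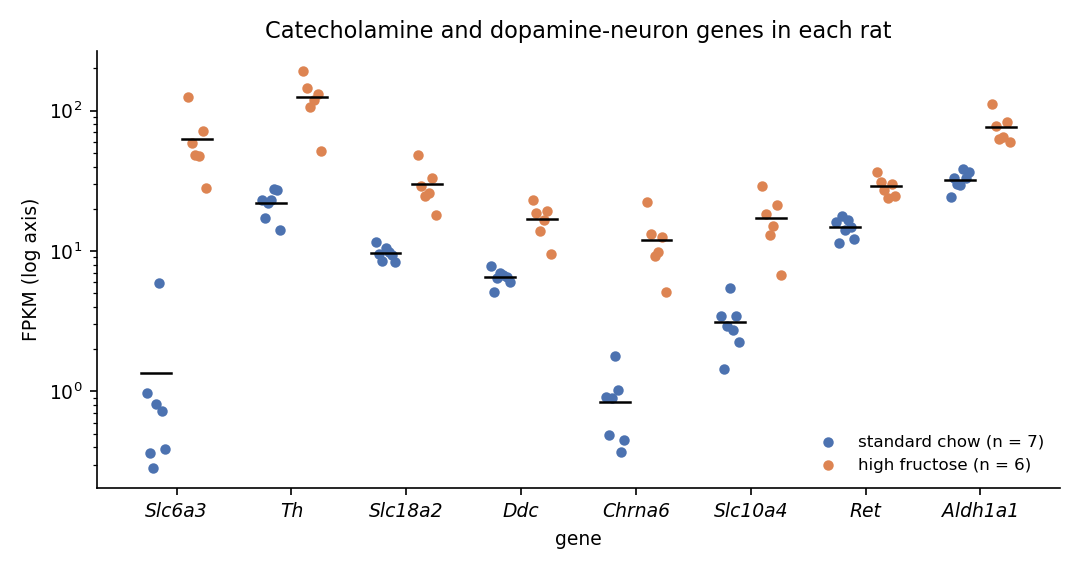
FPKM of dopamine-neuron genes in each rat (points, logarithmic vertical axis) by diet, with a bar at the mean of the 7 chow rats and of the 6 fructose rats. All 6 fructose rats lie above all 7 chow rats, for Slc6a3 between 28.3 and 125 FPKM against 0.285 to 5.95 FPKM.

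Other genes that rose with the smallest p were of mixed function. Nrgn, neurogranin, a calmodulin-binding protein of forebrain neurons, rose from 70.7 ± 13.6 to 130 ± 16 FPKM (0.88 ± 0.11, limma adjusted p = 0.00104). C1ql1, a secreted protein of the C1q family, rose by 0.92 ± 0.13. Slc39a4, a zinc transporter, and Zar1, best known from oocytes, rose by 1.80 ± 0.21 and 1.71 ± 0.24 from low levels of 0.245 and 0.135 FPKM on chow. With pseudocounts of 1 and 0.1 the rise was 1.32 and 2.70 for Slc39a4, and 1.18 and 3.06 for Zar1. For these 4 genes as well, all 6 fructose rats lay above all 7 chow rats.

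Of 17 tested genes of the thalamus, which borders the hypothalamus, 11 fell on fructose, 1 rose and 5 did not pass. Adjusted over the list alone 15 passed. Zic1, a zinc finger transcription factor, fell from 40.5 ± 11.6 to 17.3 ± 6.08 FPKM (-1.24 ± 0.23, limma adjusted p = 0.0161). The potassium channel gene Kcnc2 fell from 103 ± 29.2 to 49.6 ± 18.4 FPKM (-1.08 ± 0.23), Grid2ip, which binds a glutamate receptor, by 1.27 on the log2 scale (-1.27 ± 0.27), and Prkcd, a protein kinase C, from 220 ± 113 to 57.7 ± 51.6 FPKM (-2.32 ± 0.60). Calb2, calretinin, was the member that rose (0.51 ± 0.11). The list median was -1.20 (camera adjusted p = 3.71e-08, adjusted p = 0.336 with an estimated correlation), and its level was 5.28 ± 0.44 on chow and 4.30 ± 0.69 on fructose, lower than the chow mean in 6 of 6 fructose rats (exact permutation p = 0.0105, adjusted p = 0.0491). The diets overlapped, and the level lay below all chow rats in 3 of 6 fructose rats. The 12 calls in the list came to 1 without chow replicate 2, chow replicate 4, fructose replicate 4 or fructose replicate 6, 2 without chow replicate 7 or fructose replicate 2, 4 without chow replicate 5 and 5 without chow replicate 3. At an unadjusted p under 0.05 there were 14 or 15 in each of these fits. Kcnc2 and Grid2ip lost their calls without chow replicate 2 (limma adjusted p = 0.0576 and 0.0616), chow replicate 4 (0.0517 and 0.0582), chow replicate 7 (0.0503 and 0.0535), fructose replicate 4 (0.0657 and 0.0696) or fructose replicate 6 (0.0602 and 0.0595), and Kcnc2 also without fructose replicate 2 (0.0513).

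**Figure D3:**
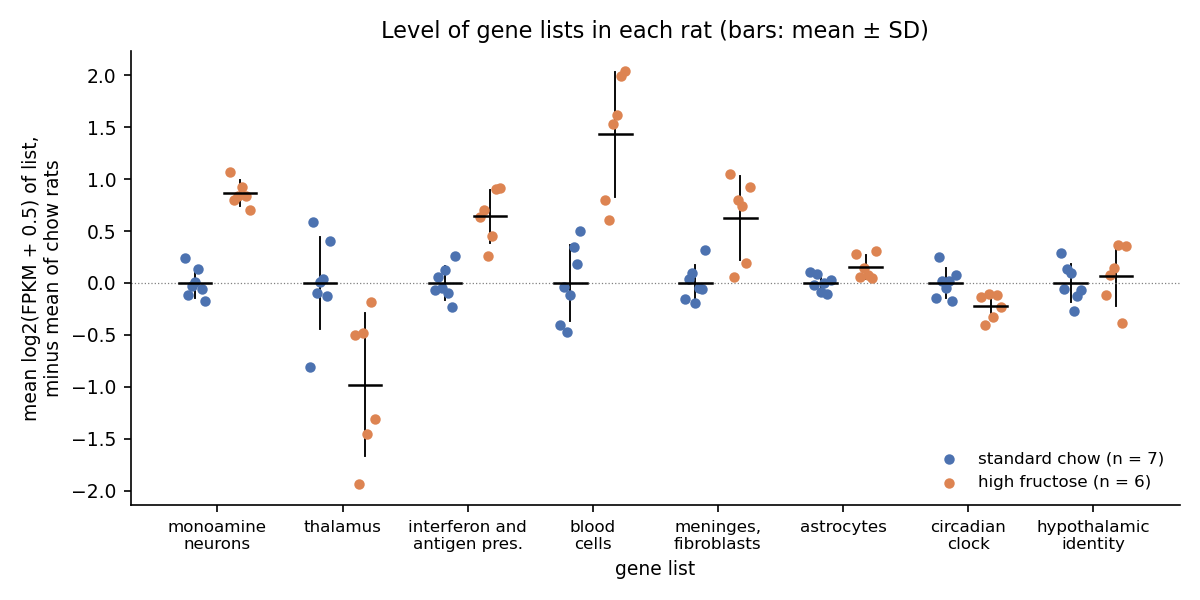
Level of gene lists in each rat (points, mean log2(FPKM + 0.5) over the tested members minus the mean of the chow rats, vertical axis) by diet, with bars at the mean ± SD of 7 chow and 6 fructose rats. Before that subtraction the blood cell level was 2.75 ± 0.37 on chow and 4.18 ± 0.60 on fructose, and the thalamus level 5.28 ± 0.44 and 4.30 ± 0.69.

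Of 16 GABA receptor genes 5 fell and 11 did not pass (8 passed adjusted over the list alone), among them Gabrd, the delta subunit (-2.24 ± 0.56), Gabra4 (-1.44 ± 0.38) and Gabbr1, a GABA-B receptor subunit (-0.27 ± 0.06). The list was lower in 6 of 6 fructose rats than the chow mean and in 4 than any chow rat (median -0.26, camera adjusted p = 0.00130, adjusted p = 0.328 with an estimated correlation). Of 73 potassium channel genes 11 fell and 62 did not pass, 15 adjusted over the list alone, with Kcnj12 at -0.78 ± 0.15 and Kcnd2 at -0.38 ± 0.08 (list median -0.05, camera adjusted p = 0.0196, adjusted p = 0.506 with an estimated correlation). Vesicle genes such as Vamp2 (-0.23 ± 0.05) and Rims1 (-0.44 ± 0.11) were the 2 of 25 that fell, with 8 passing adjusted over the list alone (camera adjusted p = 0.000536, adjusted p = 0.337 with an estimated correlation). The list of 10 markers of GABA and glutamate neurons was lower as a whole (camera adjusted p = 0.0385, adjusted p = 0.274 with an estimated correlation). With the thalamus level as a covariate, chosen after the data were seen, the GABA receptor list stood at a camera adjusted p of 0.00803. The marker list stood at 0.0165, the potassium channel list at 0.8289 and the vesicle list at 0.449. With the blood level the GABA receptor list stood at 0.0319 and the marker list at 0.930, and with the dopamine-neuron level at 0.524 and 0.1295. All of these rest on the preset correlation. Gabrd and Prkcd, a gene of the thalamus list, were both lowest in fructose replicate 2 (2.298 and 7.827 FPKM). In chow replicate 7 they stood at 110.9 and 358.2 FPKM. Their relation was not tested, so a fall of GABA receptor genes apart from the thalamus genes is not shown.

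With 1 rat left out, the calls among potassium channel genes came to 1 without chow replicate 2, 4 or 7 or fructose replicate 4 or 6, 2 without fructose replicate 2 and 4 without chow replicate 5, against 11 in all rats. Among GABA receptor genes limma called 0 without chow replicate 2, 4 or 7 or fructose replicate 2 or 4, with 8 or 9 at an unadjusted p under 0.05, 1 without chow replicate 3 or 5 or fructose replicate 6, and 2 without chow replicate 6. The vesicle genes gave 0 calls without chow replicate 2, 4 or 7 or fructose replicate 2, 4 or 6, with 11 to 16 at an unadjusted p under 0.05, 1 without chow replicate 3 or 5 or fructose replicate 3, 4 without chow replicate 6 and 7 without chow replicate 1. The potassium channel list was not called without fructose replicate 2 (adjusted p = 0.1304) or with no filter on low values (0.0524). The list of GABA and glutamate markers was not called without chow replicate 1 (0.105), chow replicate 3 (0.0840), fructose replicate 3 (0.0652) or fructose replicate 5 (0.0735).

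Most of the genes that fell with the smallest p changed by less than 2-fold. Zic4, a neighbour of Zic1 in the same family of transcription factors, fell by more than that, from 5.05 ± 1.38 to 2.09 ± 0.439 FPKM (-1.08 ± 0.16). Dbc1 (-0.75 ± 0.13), Tox (-0.61 ± 0.10), a transcription factor, and Ptprn2 (-0.49 ± 0.08), a protein of secretory vesicles, also fell. Ywhaz, the 14-3-3 zeta protein, fell from 858 ± 70.7 to 665 ± 52.5 FPKM (-0.37 ± 0.06). Mal2, Lzts1, Fem1c, Dpp10, Tmem47, Ttc19 and Lrrtm2 fell by 0.35 to 0.53 on the log2 scale. For all of these genes but Ttc19, where 5 of 6 fructose rats did, all 6 fructose rats lay below all 7 chow rats.

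Of 25 tested genes of the interferon response and antigen presentation, 11 rose on fructose and 14 did not pass. Adjusted over the list alone 16 rose. Mx2, an interferon-induced GTPase, rose from 10.97 ± 3.36 to 27.5 ± 7.94 FPKM (1.30 ± 0.21, limma adjusted p = 0.00700), with all 6 fructose rats above all 7 chow rats. Irf7, a transcription factor of the interferon response, rose by 1.35 ± 0.30, and Isg15, an interferon-induced modifier, by 1.06 ± 0.24. B2m, the light chain of MHC class I, rose from 238 ± 14.4 to 289 ± 20.7 FPKM (0.28 ± 0.06) and Cd74, the invariant chain of MHC class II, from 3.23 ± 0.911 to 6.15 ± 1.58 FPKM (0.84 ± 0.18). The list median was 0.50 (camera adjusted p = 1.33e-14, adjusted p = 0.106 with an estimated correlation), and its level lay higher in 6 of 6 fructose rats than in any chow rat (exact permutation p = 0.000583, adjusted p = 0.00894). The 11 calls came to 1 without fructose replicate 6, 2 without chow replicate 2, 3 without chow replicate 5, 4 without chow replicate 4 or fructose replicate 4, 5 without fructose replicate 2 and 6 without chow replicate 7. B2m was lost without chow replicate 2 (adjusted p = 0.0512), fructose replicate 4 (0.0569) and fructose replicate 6 (0.0503), and Cd74 without these (0.0610, 0.0703 and 0.0693) and chow replicate 4 (0.0594).

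The globin genes Hba1 and Hba2 rose by 1.93 ± 0.31 and 2.00 ± 0.35, Hba1 from 176 ± 54.6 to 738 ± 344 FPKM (limma adjusted p = 0.00744), and the row of Hbb joined with a copy rose by 1.96 ± 0.34. How reads divide between these copies is uncertain. Of 11 blood genes 6 rose and 5 did not pass, with 9 rising adjusted over the list alone, and the blood level was 2.75 ± 0.37 on chow and 4.18 ± 0.60 on fructose, higher in 6 of 6 fructose rats than in any chow rat (camera adjusted p = 8.16e-10, adjusted p = 0.122 with an estimated correlation). A list of leukocyte genes differed by 0.06 (exact permutation p = 0.119), with 0 of 7 genes called by limma and 2 at an unadjusted p under 0.05. Of 14 genes of the meninges and fibroblasts 5 rose and 9 did not pass, with 11 rising adjusted over the list alone (median 0.56, camera adjusted p = 8.16e-10, adjusted p = 0.264 with an estimated correlation). They included the growth factor Igf2 (1.27 ± 0.25), the proteoglycan Fmod (1.18 ± 0.26) and Col1a1, type I collagen (0.91 ± 0.22), and Col5a1 (1.03 ± 0.17) and Col6a2 (0.63 ± 0.11) rose among 20 collagens, of which 4 rose and 16 did not pass, with 10 passing adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.336 with an estimated correlation). The meningeal calls came to 0 without fructose replicate 4, with 11 at an unadjusted p under 0.05, 1 without chow replicate 4 or fructose replicate 6, and 2 without chow replicate 2, 3, 5 or 7 or fructose replicate 1 or 3. The collagen calls came to 2 without chow replicate 2, 3, 4 or 7 or fructose replicate 3, 4 or 6.

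Igf2 was lost without fructose replicate 4 (limma adjusted p = 0.0542), and Fmod without chow replicate 4 (0.0634), chow replicate 7 (0.0503), fructose replicate 4 (0.0636) or fructose replicate 6 (0.0741). Col1a1 was called in 3 of the 13 fits with 1 rat left out, with an adjusted p between 0.0506 and 0.0921 in the others. It lost its call without chow replicates 2, 3, 4, 5, 6 or 7 and without fructose replicates 1, 3, 4 or 6. With the blood level as a covariate, chosen after the data were seen, the interferon list stayed at an adjusted p of 0.000122, the meningeal list at 0.0112 and the collagen list at 0.890.

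Of the astrocyte, oligodendrocyte precursor, myelin and microglia genes, limma called 3 of 16, 2 of 10, 0 of 19 and 0 of 18. The astrocyte genes Gfap, an intermediate filament (147 ± 24.1 to 228 ± 51.6 FPKM, 0.62 ± 0.14, limma adjusted p = 0.0323), Aqp4, a water channel (0.27 ± 0.06), and Mlc1 (0.16 ± 0.04) rose, and 13 of 16 astrocyte genes did not pass, with 7 rising adjusted over the list alone (median 0.12, camera adjusted p = 0.000136, adjusted p = 0.146 with an estimated correlation). The level of oligodendrocyte precursor genes was 4.70 ± 0.09 on chow and 4.91 ± 0.12 on fructose (exact permutation p = 0.00524, adjusted p = 0.0345), and 2 of 10, C1ql1 and Sox8, rose, also 2 adjusted over the list alone (camera adjusted p = 0.000536, adjusted p = 0.336 with an estimated correlation). Sox8 kept its call only without chow replicate 1 or 3 or fructose replicate 3. In the myelin list limma called 0 of 19 genes by either adjustment and 2 at an unadjusted p under 0.05, with a list median of 0.17 (camera adjusted p = 0.000158, adjusted p = 0.506 with an estimated correlation, exact permutation p of the level = 0.115). Mbp stood at 7826 ± 1117 and 9210 ± 1531 FPKM, with an adjusted p of 0.310, Cnp at 0.251 and Gsn at 0.168. The ependymal list was higher by camera (median 0.26, adjusted p = 0.00151, adjusted p = 0.328 with an estimated correlation), as were the endothelium (median 0.11, adjusted p = 0.00323) and the microglia (median 0.13, adjusted p = 0.0158), both with an adjusted p = 0.336 with an estimated correlation. Limma called 0 genes in each of them, with 4, 4 and 5 at an unadjusted p under 0.05. The microglia were not called without fructose replicate 5 (0.0523). With the blood level as a covariate, chosen after the data were seen, the ependymal list stood at 0.0755, the endothelium at 0.344 and the microglia at 0.628.

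Among the inflammation genes, 1 of 21, Tnfrsf1a, rose (0.32 ± 0.09), and 1 adjusted over the list alone (camera adjusted p = 0.00406, adjusted p = 0.146 with an estimated correlation). Tnfrsf1a kept its call only without fructose replicate 3 or 5. The list was not called after quantile normalization (0.0552). Gfap was lost without chow replicate 2 (adjusted p = 0.0693), chow replicate 4 (0.0691), chow replicate 5 (0.0501), fructose replicate 4 (0.0795) or fructose replicate 6 (0.0775). With the level of the thalamus, dopamine-neuron or blood list as a covariate, chosen after the data were seen, Gfap stood at 0.71 ± 0.19, 0.90 ± 0.46 and 0.30 ± 0.26 (adjusted p = 0.204, 0.691 and 0.650). Aqp4 was lost without chow replicate 2 (0.0616), chow replicate 4 (0.0601), fructose replicate 4 (0.0588) or fructose replicate 6 (0.0696), and Mlc1 in 12 of the 13 fits with 1 rat left out, with an adjusted p of up to 0.107 without fructose replicate 6. Mlc1 was kept without chow replicate 1, and lost with no filter on low values (0.0542) or with robust empirical Bayes (0.0533).

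Of 17 clock genes 4 fell, 1 rose and 12 did not pass, with 8 passing adjusted over the list alone. Nfil3, a repressor, fell to 7.52 ± 1.29 FPKM on fructose (-0.40 ± 0.10, limma adjusted p = 0.0394), Npas2, a partner of Arntl, by 0.73 (-0.73 ± 0.19), Bhlhe40 by 0.38 (-0.38 ± 0.10) and Arntl itself by 0.43 (-0.43 ± 0.11), whereas Per3 rose (0.28 ± 0.06). The list was below the chow mean in 6 of 6 fructose rats and below all chow rats in 3 (median -0.27, camera adjusted p = 0.000173, adjusted p = 0.336 with an estimated correlation). It stood at 0.804 with the thalamus level as a covariate, chosen after the data were seen. The chaperones Hsph1 (-0.39 ± 0.09), Dnajb5 (-0.36 ± 0.09) and Hspa4 (-0.19 ± 0.05) fell among 19 heat shock genes, of which 16 did not pass, with 5 passing adjusted over the list alone (camera adjusted p = 0.0196, adjusted p = 0.506 with an estimated correlation, exact permutation p of the level = 0.106). The 3 calls came to 0 without chow replicate 2, 4, 5 or 7 or fructose replicate 2, 4 or 6, with 6 to 8 at an unadjusted p under 0.05. The heat shock list was not called without chow replicate 5 (0.0605) or after quantile normalization (0.0552). The unfolded protein response was lower by camera (median -0.07, adjusted p = 0.00929, adjusted p = 0.336 with an estimated correlation) and the cytosolic ribosomal proteins were higher (median 0.06, adjusted p = 0.000242, adjusted p = 0.626 with an estimated correlation). Limma called 0 of 23 and 0 of 80 of their genes, with 4 in each at an unadjusted p under 0.05.

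Limma called 0 clock genes without chow replicate 2 or 4 or fructose replicate 4 or 6, with 8 at an unadjusted p under 0.05, 1 without chow replicate 5 or 7 or fructose replicate 1 or 2, 2 without chow replicate 3 and 3 without chow replicate 6 or fructose replicate 3. Nfil3 lost its call without chow replicate 2, 4, 5 or 7 or fructose replicate 1, 4 or 6 (adjusted p up to 0.0930). Bhlhe40 lost it without these or without chow replicate 3 or fructose replicate 2 (up to 0.104), and Npas2 kept it only without chow replicate 1 or fructose replicate 5 (up to 0.104). With no filter on low values Nfil3 (0.0548), Npas2 (0.0604) and Bhlhe40 (0.0595) lost their calls, and Bhlhe40 also after quantile normalization (0.0523). Fos, an immediate early gene, stood at 23.7 ± 6.24 on chow and 14.2 ± 3.54 FPKM on fructose (-0.72 ± 0.19, limma adjusted p = 0.0490). With 1 rat left out it was called only without chow replicate 6 or fructose replicate 3, and its adjusted p lay between 0.0321 and 0.104. It was also lost at a pseudocount of 0.1 (0.0507) and with no filter on low values (0.0651). The same held after quantile normalization (0.0548) or median-ratio scaling (0.0507), and with robust empirical Bayes (0.0535). With the level of the thalamus, dopamine-neuron or blood list as a covariate, chosen after the data were seen, its log2 fold change was -0.53 ± 0.26, -1.29 ± 0.62 and -0.21 ± 0.34 (adjusted p = 0.628, 0.654 and 0.842). Of 24 immediate early genes 2, Fos and Dusp1 (-0.78 ± 0.20), fell and Nr4a2 (1.23 ± 0.32) rose, and the list was not called (camera adjusted p = 0.458). Its 3 calls came to 0 without chow replicate 2, 4 or 7 or fructose replicate 2, 4 or 6, with 6 to 9 at an unadjusted p under 0.05, and 1 without chow replicate 3 or 5 or fructose replicate 1 or 3.

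Genes of feeding control moved in different directions. Among 25 receptors for feeding hormones and peptides, 5 rose and 2 fell, with 10 passing adjusted over the list alone. The incretin receptor Gipr rose from 2.88 to 4.93 FPKM (0.70 ± 0.12, limma adjusted p = 0.00874), the melanocortin receptor Mc3r by 0.98 ± 0.20 and the ghrelin receptor Ghsr by 1.01 ± 0.24, whereas Npy1r, a neuropeptide Y receptor, fell (-0.88 ± 0.17) together with Ramp3 (-1.68 ± 0.42), which is on the thalamus list too. The list had a median of 0.08 (camera adjusted p = 0.00920, adjusted p = 0.336 with an estimated correlation) and stood at 0.889 with the thalamus level as a covariate, chosen after the data were seen. The 7 calls came to 1 without chow replicate 2 or fructose replicate 4, 2 without chow replicate 4 or fructose replicate 6, 3 without chow replicate 5 or 7 and 4 without fructose replicate 2 or 3. The feeding neuropeptides were not called as a list, where the median was -0.04 and the mean 0.04 (camera adjusted p = 0.458), although the peptide genes Ucn, urocortin (1.94 ± 0.42), Adcyap1 (1.02 ± 0.24), Tac1 (0.65 ± 0.17) and Bdnf (0.48 ± 0.13) rose. These 4 calls came to 0 without chow replicate 2, 4 or 7 or fructose replicate 2 or 4, with 7 to 9 at an unadjusted p under 0.05. They came to 1 without fructose replicate 3 or 6 and 2 without chow replicate 3 or fructose replicate 1. Among fructose rats Ucn was highest in replicate 1 (8.79 FPKM) and lowest in replicate 6 (0.318 FPKM). The level of the midbrain dopamine neuron list was highest and lowest in the same rats (4.17 and 3.11), and their relation was not tested.

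The classical peptides of the hypothalamus did not pass. Pmch, melanin-concentrating hormone, stood at 5107 ± 1083 FPKM on chow and 3494 ± 1782 FPKM on fructose (limma adjusted p = 0.197), and Hcrt, orexin, at 700.4 ± 171 and 527 ± 294 FPKM (0.331). Pomc (0.35 ± 0.35, adjusted p = 0.661), Agrp (-0.33 ± 0.28, 0.582), Cartpt (-0.16 ± 0.27, 0.812), Trh (-0.65 ± 0.53, 0.555) and Crh (-0.07 ± 0.20, 0.891) differed by less than the spread between rats. Oxt (-1.99 ± 1.44, 0.494) and Avp (-1.61 ± 1.53, 0.634) had the widest errors of the fixed set. Npy was listed at 0 in all 13 rats.

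Slc2a5, the fructose transporter, stood at 3.99 ± 0.547 FPKM on chow and 3.93 ± 1.06 FPKM on fructose (-0.05 ± 0.15, limma adjusted p = 0.909), and Khk, ketohexokinase, at 10.2 ± 1.42 and 11.4 ± 1.58 FPKM (0.15 ± 0.10, 0.455). Limma called 0 of 17 genes of glucose and fructose transport and fructose metabolism, with 1 at an unadjusted p under 0.05 (camera adjusted p = 0.560). Insr (0.05 ± 0.11), the joined row of Lepr and Leprot (0.04 ± 0.08), Mc4r (0.18 ± 0.12), Nr3c1 (-0.09 ± 0.05) and Fkbp5 (0.10 ± 0.10) had adjusted p of 0.874, 0.827, 0.464, 0.396 and 0.636. The lists of glycolysis (camera adjusted p = 0.127), lipogenesis (0.560), cholesterol synthesis (0.371), oxidative phosphorylation (0.0560), energy sensing (0.465), insulin and growth factor signalling (0.101), the stress axis (0.291), glucocorticoid responsive genes (0.510) and oxidative stress (0.357) were not called. Of 20 stress axis genes 3 rose, namely Ucn, Adcyap1 and Bdnf, which are on the feeding neuropeptide list too. Of 31 insulin and growth factor genes 1 rose and 1 fell, of 20 glucocorticoid responsive genes 1 fell, and of 24 oxidative stress genes 1 rose and 1 fell. These calls numbered, with 1 rat left out, 0 to 3, 0 to 4, 0 to 2 and 1 to 3. In the other 5 lists limma called 0 genes.

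Other lists not called were glutamate receptors (camera adjusted p = 0.0536), voltage-gated sodium and calcium channels (0.0695), pericytes (0.0607), the choroid plexus (0.163), hypothalamic regional identity (0.183), tanycytes (0.430), the proteasome (0.560), cortex, hippocampus and amygdala (0.560), the striatum (0.634), histones (0.847) and reproductive peptides (0.967). Of the 22 planned fits, camera called glutamate receptors in 9, oxidative phosphorylation in 8, sodium and calcium channels in 6, pericytes in 5 and insulin and growth factor signalling in 3. It called glycolysis, the proteasome, the choroid plexus and hypothalamic identity in 1 each. Among genes of the striatum 4 of 17 rose and 1 fell, of cortex, hippocampus and amygdala 3 of 18 rose, and of hypothalamic identity 2 of 25 rose. Of sodium and calcium channels 1 of 32 rose and 4 fell, and of glutamate receptors 1 of 26 fell. These calls numbered, with 1 rat left out, 2 to 7, 2 to 6, 0 to 4, 0 to 8 and 0 to 4. In the cortex and histone lists the median (-0.07 and -0.02) and the mean (-0.05 and -0.01) were below 0 while camera's direction was up. In the reproductive list the median was 0.01 and the mean -0.18, and in the striatum list the median -0.11 and the mean 0.00. The pituitary list was higher by camera (median 0.19, adjusted p = 0.0273, adjusted p = 0.336 with an estimated correlation), where 1 of 7 genes, Nkx2-2, rose (0.32 ± 0.08) and 2 passed adjusted over the list alone. Nkx2-2 kept its call only without chow replicate 1 or fructose replicate 5, and limma called 0 pituitary genes in 10 of the 13 fits with 1 rat left out. The list was not called without chow replicate 7 (0.0565) or fructose replicate 4 (0.156).

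In all, camera called 23 of 46 lists, 15 higher and 8 lower on fructose, with 27 at an unadjusted p under 0.05. With an estimated correlation 0 were called by camera, and 7 had an unadjusted p under 0.05. Fry called 9, and the exact permutation test of list levels 12.

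With the level of a list as a covariate, chosen after the data were seen, limma called 30 genes for the thalamus, 0 for dopamine neurons and 37 for blood, against 466. The levels of dopamine neurons and of blood separate the diets fully, so those fits compare no rats at a shared level. With the thalamus, dopamine-neuron and blood levels in turn, Mx2 stood at 1.29 ± 0.29, 2.37 ± 0.61 and 1.30 ± 0.40 (adjusted p = 0.0997, 0.550 and 0.149) against 1.30 ± 0.21. Th stood at 2.39 ± 0.33, -0.18 ± 0.32 and 3.22 ± 0.39 (0.00683, 0.935 and 0.00492), and Slc6a3 at 5.55 ± 0.60, 1.44 ± 0.91 and 5.63 ± 0.84 (0.00199, 0.757 and 0.0127). Hba1 stood at 2.49 ± 0.38, 4.09 ± 0.83 and 0.18 ± 0.24 (0.00904, 0.503 and 0.809), and Zic1 at -0.51 ± 0.16, -0.97 ± 0.77 and -1.77 ± 0.42 (0.327, 0.800 and 0.0841). Th and Slc6a3 are members of the dopamine-neuron list, Hba1 of the blood list and Zic1 of the thalamus list. With its own list as the covariate each was adjusted for a mean that holds it, so its drop there was built in.

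Among the 23 lists, camera with the thalamus level as a covariate did not call the ribosomal proteins (adjusted p = 0.987), heat shock genes (0.636), pituitary and inflammation (0.360 each), ependymal cells (0.300), thalamus (0.163) and microglia (0.0784). The feeding receptors, potassium channels, clock and vesicle genes are given above. With the dopamine-neuron level it did not call the feeding receptors (0.736), potassium channels (0.571), GABA receptors and endothelium (0.524 each), monoamine and histamine neurons (0.506), and clock (0.452). The same held for the pituitary (0.334), heat shock genes (0.228), GABA and glutamate markers (0.1295) and astrocytes (0.102). It also did not call the unfolded protein response (0.0759), oligodendrocyte precursors (0.0608) and microglia (0.0551). With the blood level it did not call the pituitary (0.621), the ribosomal proteins (0.439), blood itself (0.826) and vesicle genes (0.0888). The markers, collagens, microglia, endothelium and ependymal cells are given above. The thalamus and blood lists were each adjusted for their own level, and the monoamine list shares genes with the dopamine-neuron list. Losses of those calls were thus built in and tell nothing of a cause. Lists outside the 23 were called too. With the thalamus level these were the reproductive peptides (3.53e-05), pericytes (0.000426), feeding neuropeptides (0.00256) and cortex, hippocampus and amygdala (0.00948). With the dopamine-neuron level they were cholesterol synthesis (1.11e-06), oxidative phosphorylation (0.000667), reproductive peptides (0.00180), tanycytes (0.0169) and hypothalamic identity (0.0188). With the blood level they were cholesterol synthesis (0.000177), hypothalamic identity (0.0362) and feeding neuropeptides (0.0426).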

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

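The tests of midbrain tissue, of a response of dopamine neurons, of library scaling and of a varying share of thalamus were chosen only after the results were seen. The tests of blood and of midbrain tissue in the interferon genes, and the splits of the rats, were chosen before, but the bound for the blood test was made stricter afterwards.

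In 10 of 238 groups of 6 or 7 rats a single rat lay far from the others, where chance gives about 1 in 20 groups, or 11.9. Chow replicate 5 had 5.95 FPKM of Slc6a3 against 0.285 to 0.978 in the other chow rats, and fructose replicate 1 had 7.92 FPKM of Chrnb3 against 1.78 to 2.88. Fructose replicate 2 had 17.6 FPKM of Dpp10 against 21.4 to 23.9, and chow replicate 3 had 1.92 FPKM of Agrp against 0.302 to 0.723. Fructose replicate 1 had 21.0 FPKM of Nr3c1 against 17.7 to 18.8, and fructose replicate 6 had 7.61 FPKM of Fos against 13.5 to 18.1. Among list levels, chow replicate 1 lay at 7.45 for glycolysis against 7.56 to 7.62 and at 2.62 for ependymal cells against 2.21 to 2.37. Fructose replicate 5 lay at 5.80 for the unfolded protein response against 5.73 to 5.75, and fructose replicate 4 at 3.64 for the pituitary against 2.43 to 2.79.

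Chance is unlikely to give the number of genes changed by diet, but 100 of the 1716 splits cannot exclude it. The splits also say nothing on cage, batch or dissection tied to diet. Of 100 splits of the 13 rats into 7 and 6, the real one included, 1 gave as many genes as the real 466, and the highest of the others gave 408, with 4 of the real fructose rats on 1 side. For the gene lists, 2 of the 100 splits gave as many calls, the real one with 23 and the highest other with 24. The median of the other splits was 12 lists, so camera with its preset correlation calls many lists for splits unrelated to diet. Chance is therefore not excluded for the number of lists, though few splits reached it.

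Genes of dopamine neurons were higher in every fructose rat, with 19 of 22 tested genes rising. Library scaling is argued against, since 18 of the 19 stayed called after quantile normalization. Midbrain tissue in the dissected piece is a candidate explanation, because regional genes outside dopamine neurons, 15 of 18 of them above 0 in these rats, were higher too (exact permutation p = 0.00466), though at levels near the floor. At equal level of those regional genes the dopamine-neuron level stayed 1.18 ± 0.20 (SE) higher on fructose, but the regional genes themselves differed by diet and are measured with error, so a response of dopamine neurons to the diet and midbrain tissue cannot be told apart, and this test replaced another after that one's value had been seen. The hypothalamus holds dopamine neurons of its own, and Th stood at 22.1 FPKM on chow. Levels of the other list members on chow were mixed. Aldh1a1 stood at 32.2 and Slc18a2 at 9.68 FPKM, but Slc6a3 at 1.36, Chrna6 at 0.846, Foxa2 at 0.248 and Pitx3 at 0.0819 FPKM. On fructose Aldh1a1 stood at 76.42, Slc18a2 at 29.85, Slc6a3 at 63.37 and Chrna6 at 12.02 FPKM. Foxa2 stood there at 2.25 ± 1.248 and Pitx3 at 1.9998 ± 1.535 FPKM (SD, n = 6). For Foxa2 6 of 6 fructose rats lay above all chow rats, and for Pitx3 5 of 6. Members near the floor on chow thus rose, as did members expressed there. Near absence on chow goes with midbrain tissue, but whether dopamine neurons of the hypothalamus can raise these genes was not tested. The levels on chow therefore do not decide between the explanations, and the diet itself stays open.

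Thalamus genes were lower on fructose. The list kept a camera adjusted p of 6.73e-09 after quantile normalization. This tests scaling little, because camera compares the list with all other genes and scaling moves the genes of a library alike. Scaling is argued against by the list median, -1.16 after quantile normalization, against a median of 0.000851 over all genes in the main fit. The call itself rests on the preset correlation (camera adjusted p = 0.336 with an estimated correlation). A share of thalamus that varies from piece to piece may account for it, but the test made of it cannot decide. It compared 2 parts of the list, each with every other member, and any cause shared by the list's genes would make these correlate. Camera's estimated correlation between those genes was 0.640. The parts moved together among rats of 1 diet, with Pearson r = 0.930 in 7 chow rats (permutation p = 0.00556, adjusted p = 0.0139 over 5 relations). Spearman's rho was 0.679 there (permutation p = 0.110, adjusted p = 0.274) and r was 0.638 without the 2 farthest rats, so the relation rests in part on those, while in 6 fructose rats r was 0.974 (permutation p = 0.00556, adjusted p = 0.0139), rho 0.943 (permutation p = 0.0167, adjusted p = 0.0833) and r 0.960 without the 2 farthest. Why the share would differ by diet, and an effect of the diet on thalamic genes, stay open and untested.

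Interferon and antigen presentation genes were higher on fructose, and so were blood genes. With the blood level as a covariate the list median went from 0.50 to 0.31. The list stayed called with the preset correlation (camera adjusted p = 0.000122, against 1.33e-14 without the covariate). With an estimated correlation it was not called without the covariate (camera adjusted p = 0.106), and that setting was not run with the covariate. The difference of the list level went from 0.64 ± 0.12 to 0.49 ± 0.22 (SE). The list thus meets the bound written before the result was seen (still called, with more than 50% of the median left). Mx2 stood at 1.30 ± 0.40 against 1.30 ± 0.21, with its call lost (limma adjusted p = 0.149). The remaining difference of the level also passes 2 SE, though not the small-sample 95% bound put in its place afterwards. The written bound was wrong for this design, because the blood level separated the diets fully (2.28 to 3.26 in chow rats, 3.36 to 4.79 in fructose rats) and no rats are compared at equal blood level. None of these values therefore counts against blood, and blood cannot be told apart from the diet here. Within diets the list level had r = 0.250 with the blood level in 6 fructose rats (permutation p = 0.618, rho 0.486 with p = 0.356, r 0.994 without the 2 farthest) and r = 0.252 in 7 chow rats (permutation p = 0.585, rho 0.0714 with p = 0.906, r -0.40 without the 2 farthest), among 5 relations with adjusted p of 0.773 for both r. Midbrain tissue stays open as well, since r with the dopamine-neuron level in 6 fructose rats was -0.13 (permutation p = 0.850, rho -0.029 with p = 1, r 0.963 without the 2 farthest), which decides nothing.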

How the results depend on the processing

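The fits with a list level as a covariate were chosen after the data were seen, and the other settings before. The 466 genes came to 441 and 468 with other pseudocounts, 426 at a mean of at least 2 FPKM, 426 after quantile normalization, 446 after median-ratio scaling and 419 with robust empirical Bayes. Without a filter there were 308, 149 of them lower, over 14412 genes tested. Array weights gave 1019 genes, 376 higher and 643 lower, an adjusted p under 0.1 gave 915, and the exact permutation test gave 0 (2223 unadjusted, smallest adjusted p 0.0663). With the thalamus level as a covariate limma called 30 genes, 20 higher and 10 lower, and with the blood level 37, 19 higher and 18 lower. The blood level and the dopamine-neuron level each separate the diets fully. With the latter it called 0, with 0 higher and 0 lower (904 at an unadjusted p under 0.05), and 15 lists in place of 23. The lists came to 0 with an estimated correlation (7 unadjusted) and 9 by fry (20 unadjusted). The causes of these differences were not tested. With 1 rat left out there were 83 to 859 genes, 61 to 293 higher and 21 to 566 lower, 22 to 26 lists by camera, 3 to 14 list levels, and 21.96% to 27.1% of variance between diets. The lowest gene count was without fructose replicate 4 and the highest without chow replicate 1, and list levels numbered 3 without chow replicate 2. Over the 22 planned fits of limma, 59 genes were called each time, 40 higher and 19 lower, and 17 lists. Of the values of named genes, 519 at other settings and 771 with 1 rat left out kept direction and side of the threshold, 11 and 92 lost a call, and 0 and 7 turned direction. Those that turned were not called in any fit: Crh at -0.07 ranged from -0.15 to 0.0557, Insr at 0.05 from -0.0195 to 0.0922, Slc2a5 at -0.05 from -0.14 to 0.0641 and Cartpt at -0.16 from -0.31 to 0.0835 with 1 rat left out, and the cause was not tested. No paired analysis was possible because the replicate numbers follow accession order and the labels tie no rat of 1 diet to a rat of the other. Depth per library is unknown, so how far it limits low genes could not be given.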

Other observations

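The genes and values below were chosen after the data were seen, and no test here was planned. Foxb1, a marker of the mammillary region, rose from 2.43 ± 0.652 to 5.51 ± 2.23 FPKM (SD, n = 7 and 6, 0.99 ± 0.23 on the log2 scale, limma adjusted p = 0.0320). Foxb1 lost its call without chow replicate 2 (0.0586), chow replicate 4 (0.0662), chow replicate 7 (0.0584), fructose replicate 3 (0.0518), fructose replicate 4 (0.0703) or fructose replicate 6 (0.0767). Nkx6-1 and Uncx rose by 1.24 ± 0.19 and 0.98 ± 0.17 (limma adjusted p = 0.00663 and 0.00971), with all 6 fructose rats above all 7 chow rats. Ucn, urocortin, had 0 to 0.352 FPKM in chow rats and 0.318 to 8.79 FPKM in fructose rats. In the list of cortex, hippocampus and amygdala 3 of 18 genes rose (4 rose and 3 fell adjusted over the list alone), and in the striatum list 4 of 17 rose and 1 fell (4 and 4), and neither list was called. Of these, Emx2 (0.80 ± 0.13) and Ppp1r1b, a phosphatase inhibitor of dopamine-receptive neurons (0.47 ± 0.09), rose with every rat left out in turn.

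Oxt and Avp varied more within a diet than between diets. Oxt ranged from 8.97 to 1455 FPKM among chow rats and from 2.04 to 359 FPKM among fructose rats, and Avp from 5.08 to 601 and from 0.451 to 214 FPKM. Chow replicates 1 and 4 held the highest values of both genes. Pla2g16 stood at 4.13 FPKM in chow replicate 1 and between 57.1 and 147 FPKM in the other 12 rats. Kiss1 lay between 0 and 3.00 FPKM and Ghrh between 0 and 6.59 FPKM over the 13 rats.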
